A study of Mus musculus with 23 samples.

How the data were processed

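Gene expression was measured in the prefrontal cortex of female Balb/c mice aged 8 weeks on in-house printed oligonucleotide arrays that compare 2 RNAs on 1 slide, 1 labelled with Cy3 and 1 with Cy5. One RNA came from mice injected under the skin with 100000 cells of 4T-1, a mouse mammary carcinoma line, in 100 µl of phosphate-buffered saline (PBS), and the other from mice injected with PBS alone. Tissue was taken 18, 72 or 192 h after the injection. The labels give 23 arrays. Arrays with the same time and number in the title were taken as 1 biological replicate, which gives 12 replicates: 5 at 18 h (10 arrays), 4 at 72 h (7 arrays) and 3 at 192 h (6 arrays). The series text speaks of 3 samples at 72 h, while the titles hold 4 numbers there. Whether a replicate is 1 mouse or a pool is not given in the sources used here, so p-values measure the spread between these samples, which may be partly technical.

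The deposited scanner tables hold 3 scans per array with 10080 spots each, in 48 blocks. Per the file headers, each spot has an integrated intensity in a channel A and a channel B with the local background already subtracted, and the background intensity itself. A deposited fraction per spot gives the share of its pixels that were not saturated. The image analysis program and its version are not given in the sources used here. Separate value tables by the authors hold 1 processed log ratio per spot and array. The base of that logarithm and the authors' normalization are not stated. The median of each of these columns lay between -0.00813 and 0.00653, so each array had been centred near 0, and the SD was 0.312 to 0.759 times that of the log2 ratios computed here. RNA was reverse transcribed from total RNA for 14 arrays and from poly A RNA for 9 arrays, per the labels' protocols.

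The direction of the ratios is likely rather than settled, because no header says which dye is channel A. The authors' log ratios followed channel B over A on the 7 total RNA arrays with tumour RNA in Cy5 (r across spots 0.511 to 0.847) and A over B on the 7 arrays with tumour RNA in Cy3 (r with B over A -0.857 to -0.401). The same held on the 9 poly A arrays, which all carry tumour RNA in Cy5 by their labels (r 0.493 to 0.913). Channel B was therefore read as Cy5 and every ratio was turned to tumour over PBS.

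Oligos were named through the platform annotation. On each of the 4 printings of the array, 9066 or 9074 spots had 1 gene, 12 had several genes and 994 or 1002 were unnamed. Of 8997 accessions with 1 gene, 8909 were found by gene number in a table of the GRCm38.p6 assembly, which served for names alone, and no symbol changed. The annotation was tested with the brightness of the spots. Under the deposited names, mean brightness correlated between the 2-array and the 12-array printings used for total RNA (Spearman 0.610 over 5759 genes, against -0.0133 by spot position). Between poly A and total RNA printings it correlated at 0.0492 to 0.109 by name. Copies of 1 oligo at several spots were of similar brightness on the total RNA printings (share of the variance between oligos 0.383 and 0.430) and not on the poly A printings (0.0733 and -0.0989). The oligo names of the poly A arrays thus could not be matched to the others. By an exception fixed in advance, their 5 replicates left the comparisons, which rest on the 7 replicates with a labelled dye swap: replicates 4, 5 and 6 at 18 h, 3 and 4 at 72 h, and 3 and 4 at 192 h. Both arrays of such a replicate are technical repeats of the same RNAs.

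The design, the tests, 37 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. In each scan, spots marked good in both channels, with both intensities above 0 and with at least 0.9 of their pixels unsaturated, entered the log2 ratio. Loess with a span of 0.3 over all spots of the scan removed its dependence on brightness. Ratios were averaged over the 3 scans, arrays with tumour RNA in Cy3 had their sign turned, and spots of 1 oligo were averaged. A replicate value is the mean of both arrays of the swap and needs both, so that a dye effect common to both arrays cancels. An oligo was tested at a time point with at least 2 replicate values there. The planned normexp correction was not applied, because the intensities were already background-corrected; it was run as an alternative. The saturation limit, the need for both arrays and the minimum of 2 replicates were set after the files had been seen.

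Replicate values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per time point, 1 shared estimate of the spread). The average over time and the F test of the difference between times used oligos tested at every time point. P-values were adjusted by the Benjamini-Hochberg method over the oligos tested, and a gene passed at an adjusted p under 0.05. All adjusted p-values for genes are from this limma fit, two-sided. Gene lists with at least 5 measured genes were tested with limma's camera on normal scores of the moderated statistics, with a preset correlation of 0.01 between genes. They were also tested with a correlation estimated from the residuals and with fry. For a single time point fry used only the replicates of that time, 3 at 18 h, 2 at 72 h and 2 at 192 h. It did not borrow the spread of the other times, so it has little power there. A list that fails it is not thereby shown to be unshifted. Each gene entered once, by the oligo with the most replicate values and then the brightest. Between 30 and 66 genes had several tested oligos at a time point, and the signs of these oligos differed for 27 of 49 such genes at 18 h, 30 of 66 at 72 h and 13 of 30 at 192 h. Python 3.11.15 and matplotlib 3.10.9 drew the figures.

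Named genes follow a fixed rule. For each time point and the average, the rule takes the genes past the threshold with 1 sign in every dye-swapped replicate, up to 10 per direction by size. Where fewer than 8 qualify it fills up to 8 with those of smallest unadjusted p and 1 sign in every replicate measured. For the difference between times it takes the 10 genes of smallest adjusted p, and from each list the members past the threshold or else the 3 of smallest unadjusted p at that time.

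The pipeline was tested on simulated data with 67, 67 and 66 genes changed by log2 0.5, 1 and 2 per time point. The pattern of missing values was the real one, and the noise was drawn from limma's moderated spread of each oligo. At 18 h (3442 oligos tested) it recovered 67.2% of changes of log2 0.5 and 100% of changes of log2 1 and 2. At 72 h (4228 oligos) it recovered 53.7% of changes of log2 0.5, and at 192 h (2764 oligos) 59.7%; all larger changes were recovered at both times. False calls numbered 15, 20 and 16. At each time they made up more of the calls than the rate of 0.05 that the adjustment aims at, in 1 draw of the noise. The simulation held no slide position or dye effects. Its shares hold for this many changed genes at once, which eases the Benjamini-Hochberg threshold. They do not show that a lone change of log2 1 would pass. In the data Kif5a, at 1.05 at 192 h, had an unadjusted p of 0.00192 by limma and an adjusted p of 0.9996. Its replicates stood far apart, at 0.11 and 1.99, and its SE was 0.28 against a median SE of 0.15 at that time. It thus does not show what would happen to a lone change with the usual spread. Precision is limited by the number of arrays. Of the 10080 spots, 2784 to 8900 were usable per total RNA array (median 7614.5), and the median spot signal was 0.565 to 6.76 times its local background across arrays and channels.

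Alternatives covered the background correction, the within-array normalization, each scan alone, the authors' value tables, filters on dim and saturated spots, weights and tools in limma, arrays as single observations, the printing of the arrays, the poly A replicates and leaving out each replicate. No 2 scans held identical signals, and the highest correlation of log ratios between arrays was 0.597.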

Results

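Gene expression in the prefrontal cortex was compared between mice carrying a subcutaneous inoculum of 4T-1 mammary carcinoma cells and mice given PBS, 18, 72 and 192 h after the injection. The question was whether a small peripheral tumour inoculum is followed by a change of transcript levels in this brain region, and when. Each array compared 1 tumour RNA directly with 1 PBS RNA, so a log2 ratio above 0 means a higher level after tumour cells. This direction is likely, because it rests on the labelled dyes and on the sign of the authors' value tables. The comparisons used 7 biological replicates on 14 arrays of total RNA, each replicate measured as a dye swap: 3 at 18 h, 2 at 72 h and 2 at 192 h. The number of oligos with a value on both arrays of the swap was 2331 to 6709 per replicate. No gene passed an adjusted p of 0.05 at any time point, and the values of single genes below are reported as such.

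Replicates of 1 time point shared little of their gene-by-gene pattern. Their log2 ratios correlated across genes at a median r of 0.0278 over 5 pairs (-0.126 to 0.0899), against -0.0227 over the 16 pairs from different time points (-0.239 to 0.0690); genes are not independent replicates. Within the dye swaps, both arrays read as tumour over PBS correlated below 0 in 6 of 7 swaps (median r -0.274 over the 7, from -0.597 to 0.156). The block of the slide explained 5.32% to 60.0% of the variance of the log ratios of an array (median 11.0%). These values bear on every gene named below. Whether each pair was hybridised in opposite orientations, as labelled, stays open; if not, averaging the turned arrays would cancel an effect of the tumour, and the counts of 0, the intervals and the list means below would not show an absence of change.

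At 18 h, the genes of smallest p with a positive ratio were led by Ptov1, with a log2 ratio of 0.72 ± 0.16 (SE, n = 2), Mitd1, which acts in the last step of cell division (0.64 ± 0.16), and Ndufb4, a subunit of respiratory complex I (0.53 ± 0.15). C1qtnf4, a secreted member of the C1q and TNF related family, stood at 0.46 ± 0.14 over 3 replicates, although replicate 5 gave 0.00. Hmbox1 (0.48), Ropn1l (0.51), the calpain protease Capn12 (0.47) and Lrrc34 (0.37 ± 0.12, 3 replicates) completed the higher group. The lower group held the homeobox factors Nkx6-3 (-0.72 ± 0.17) and Dlx3 (-0.58 ± 0.16), the chaperone gene Dnajb4 (-0.84 ± 0.23) and the DNA-binding factor Arid5b (-0.71 ± 0.21). It also held Ppp3cb, a catalytic subunit of the phosphatase calcineurin (-0.53 ± 0.16), the centrosomal gene Nin (-0.67 ± 0.18), the vesicle GTPase Rab2b (-0.55 ± 0.15) and Fbxl20, a substrate-binding subunit of a ubiquitin ligase (-0.56 ± 0.15). All 16 had an adjusted p of 0.747, the smallest at this time. Dnajb4 stood at -1.50 in replicate 4 and at -0.17 in replicate 6, and Arid5b at -1.27 and -0.16, so replicate 4 carried most of these sizes. With loess within blocks 5 of the 8 lower oligos had a value, with a mean log2 ratio of -0.36 in place of -0.58 for the same 5.

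Of 3442 oligos tested at 18 h, limma called 0, with 79 higher and 135 lower at an unadjusted p under 0.05 (214 in all, 172.1 being the number that chance alone gives). Limma with trend and robust settings also called 0 (178 unadjusted), as did the fit with arrays as observations and a dye term. That fit tested 7896 oligos (517 unadjusted, against 394.8 from chance alone). At every time it used a consensus correlation within swaps of -0.0079, so it counted both arrays of a replicate as nearly independent. The 95% interval of an oligo reached 0.32 to each side at the median, and 99.1% of the oligos had an interval inside -1 to 1.

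Of 23 gene lists tested at 18 h, 2 passed, both toward higher values: cytosolic ribosomal proteins (19 of 23 genes above 0, median log2 0.14, adjusted p = 0.00313) and oxidative phosphorylation (18 of 29 above 0, median 0.12, adjusted p = 0.0377). Neither held with an estimated correlation (adjusted p = 0.947 for each list), the correlation being 0.492 and 0.513. Fry, which asks whether the genes of a list move 1 way on balance, gave an adjusted p of 0.626 for each, over the 13 and 7 genes it could use. It used the 3 replicates of this time alone, so this argues little against either list. With the normexp correction that had been planned for the main fit, neither list passed by camera (adjusted p = 0.147 and 0.255, medians 0.13 and 0.10). Under median centring of the arrays in place of loess both medians turned negative (-0.13 and -0.18). Within these lists Rpl8 (0.39 ± 0.14), Rps7 (0.33 ± 0.15), Rps29 (0.31 ± 0.14), Ndufc1 (0.42 ± 0.15), Atp5k, a subunit of the ATP synthase (0.39 ± 0.15), and Ndufs4 (0.32 ± 0.15) had the smallest p, and 0 members passed adjusted over the list alone. The replicates disagreed: the mean of the oxidative phosphorylation genes was -0.22 ± 0.04 (SEM over genes) in replicate 4, 0.37 ± 0.04 in replicate 5 and 0.16 ± 0.03 in replicate 6, and that of the ribosomal protein genes was -0.20 ± 0.04, 0.31 ± 0.04 and 0.19 ± 0.03. Over the genes that both arrays of a swap hold, the list mean was higher on the array with tumour RNA in Cy5 in 7 of 7 swaps, by 0.10 to 0.46 for oxidative phosphorylation and by 0.09 to 0.44 for ribosomal proteins. Neither list passed without replicate 5 (adjusted p = 0.930 for oxidative phosphorylation and 0.695 for ribosomal proteins) or without replicate 6 (adjusted p = 0.551 for each). With loess within each block of the slide the medians were 0.02 and 0.10, and neither list passed (adjusted p = 0.220 and 0.207).

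The remaining lists at 18 h did not pass. Heat shock proteins and chaperones had 11 of 13 genes below 0 (median -0.08, adjusted p = 0.113, although the list passed in 5 alternatives, 2 of them with poly A arrays). The adjusted p was 0.947 with an estimated correlation and 0.626 by fry, over the 5 genes it could use. Dnajb4 was the only member of a list tested at this time past a threshold adjusted over the list alone. Dnajc5 (-0.54 ± 0.22) and Dnaja2 (-0.20 ± 0.17) followed. Genes of the synaptic vesicle and exocytosis had 10 of 15 below 0 (median -0.13, adjusted p = 0.161), including the membrane fusion protein gene Snap25 (-0.43 ± 0.14) and Sv2a (-0.54 ± 0.25). Immediate early genes were mixed, with Nr4a3 at 0.41 ± 0.15 and Fos at -0.38 ± 0.22 (6 of 8 above 0, median 0.04, adjusted p = 0.834). Glucocorticoid-responsive genes, which read the hormonal stress response, had 4 of 7 above 0 (adjusted p = 0.898), with Fkbp5 at 0.10 ± 0.15, Zbtb16 at 0.12 ± 0.15 and Plin4 at -0.15 ± 0.15. Of the cytokine, chemokine and NF-kB genes, 4 of 6 lay below 0 (median -0.05, adjusted p = 0.898), with Ccl4 at -0.37 ± 0.24 and Nfkbia, an inhibitor and target of NF-kB, at -0.06 ± 0.15. Astrocyte markers had 5 of 8 above 0 (median 0.01, mean -0.04, adjusted p = 0.898; Sox9 -0.41 ± 0.15, Slc1a3 0.12 ± 0.14). Endothelial markers had 4 of 5 below 0 (median -0.02, mean 0.03, adjusted p = 0.898).

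**Figure D1:**
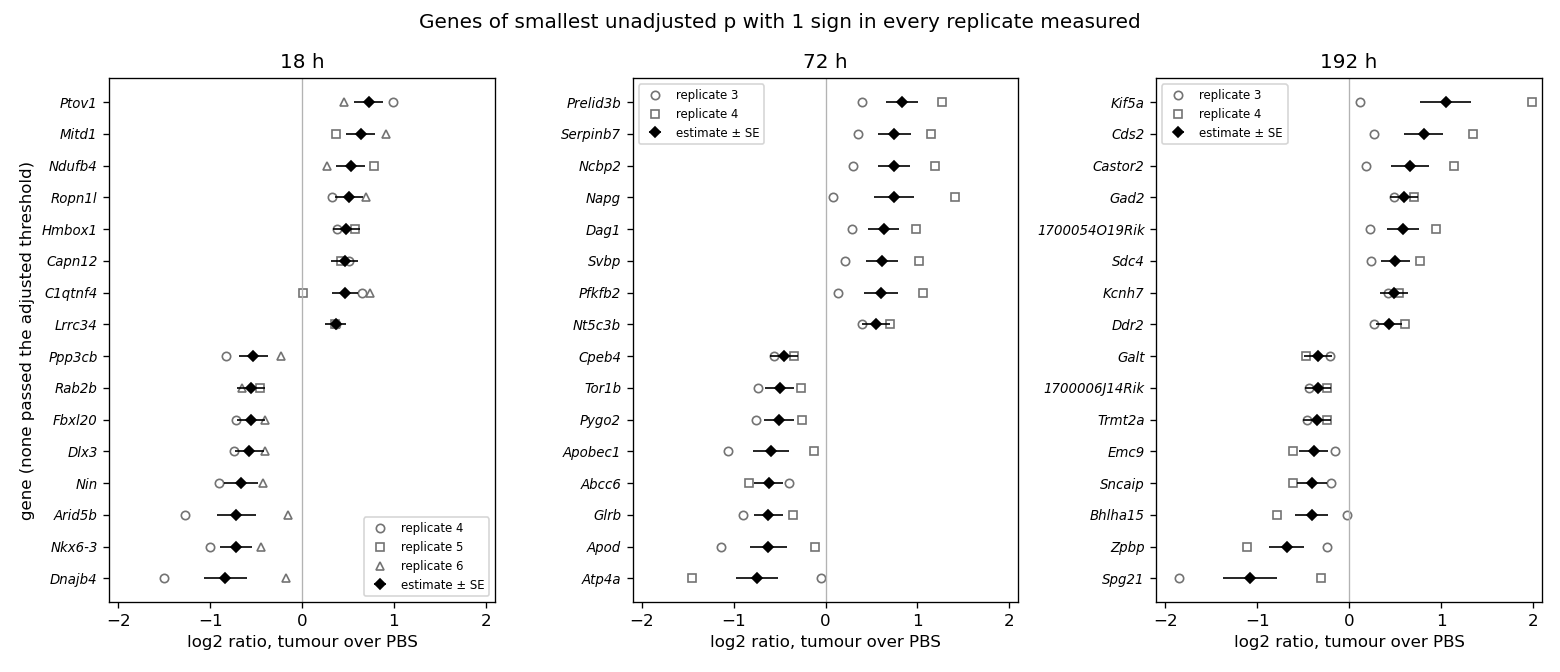
Log2 ratio of tumour over PBS (horizontal axes) for the 16 genes the fixed rule names at each of 18, 72 and 192 h; open symbols are biological replicates and filled diamonds the limma estimate with its SE. No gene shown passed an adjusted p of 0.05, and replicate 4 gave the larger positive values at 72 h (1.41 for Napg) and at 192 h (1.99 for Kif5a).

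At 72 h, the higher group was led by Prelid3b, of a family of mitochondrial lipid carriers (0.83 ± 0.17, n = 2), the nuclear cap-binding subunit Ncbp2 (0.75 ± 0.18), Serpinb7 (0.75 ± 0.18), Napg, a SNAP protein of vesicle fusion (0.74 ± 0.22), and Dag1, which encodes dystroglycan (0.63 ± 0.17). Svbp (0.61), Pfkfb2, an enzyme that sets the rate of glycolysis (0.60), and Nt5c3b (0.55) followed. The lower group held the gastric proton pump subunit Atp4a (-0.75 ± 0.23), the transporter Abcc6 (-0.62 ± 0.15), the glycine receptor subunit Glrb (-0.62 ± 0.16), apolipoprotein D (Apod, -0.62 ± 0.20) and the RNA-editing enzyme Apobec1 (-0.60 ± 0.20). Pygo2 (-0.51), Tor1b (-0.50) and Cpeb4, a regulator of mRNA polyadenylation in the cytoplasm (-0.46), completed it. Prelid3b had an adjusted p of 0.802 and the others 0.998. Replicate 4 exceeded replicate 3 in all 8 higher genes (1.26 against 0.39 for Prelid3b, 1.41 against 0.08 for Napg). Of the lower genes, Atp4a rested on replicate 4 (-1.45 against -0.05), and Apod (-1.13 against -0.11) and Apobec1 (-1.07 against -0.13) on replicate 3. Of those 8 oligos, 7 (all but that of Nt5c3b) lay in row 11 of the blocks, which held 5.56% of the tested oligos (random draws, p = 1e-04, the smallest 10000 draws can give; adjusted p = 6e-04 over 6 such tests). With loess within blocks their mean log2 ratio was 0.44 in place of 0.68.

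Of 4228 oligos tested at 72 h, limma called 0 (110 at an unadjusted p under 0.05, 59 higher and 51 lower, against 211.4 from chance alone). Limma with trend and robust settings called 0 (103 unadjusted) and the fit with arrays as observations 0 of 8168 oligos (230 unadjusted). The interval of 99.7% of the oligos lay inside -1 to 1. The estimate of the spread is shared over the time points. Without the 18 h replicate of the widest log2 ratios (SD 0.354) limma still called 0 at 72 h. However, 177 oligos then had an unadjusted p under 0.05, and the smallest adjusted p was 0.0571 in place of 0.802. Leaving out replicate 4 gave 1 call among 5891 oligos from the lone replicate 3, assumed to vary like the other time points.

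None of the 29 gene lists tested at 72 h passed. Excitatory cortical neuron and layer genes had the smallest p by camera, with 6 of 6 below 0 (median -0.14, adjusted p = 0.242; adjusted p = 0.200 with an estimated correlation and 0.967 by fry), among them the layer markers Tle4 (-0.41 ± 0.17), Otof (-0.25 ± 0.15) and Bcl11b (-0.15 ± 0.15). Oligodendrocyte and myelin genes had 4 of 5 below 0 (median -0.19, adjusted p = 0.704), with the myelin genes Mal (-0.28 ± 0.15) and Mag (-0.19 ± 0.15) and the lineage factor Olig2 (-0.28 ± 0.15). Complement and acute phase genes had 4 of 5 below 0 (median -0.17, adjusted p = 0.772), with C1qb at -0.30 ± 0.17 and Serpina3n at -0.32 ± 0.22. Microglia markers had 4 of 7 below 0 (median -0.10, adjusted p = 0.819), with Gpr34 at 0.34 ± 0.16 and Olfml3 at -0.24 ± 0.15. Cytokine, chemokine and NF-kB genes were split 5 above and 6 below 0 (adjusted p = 0.819; Cxcl2 -0.28 ± 0.15, Socs3 0.20 ± 0.15). Endothelial and vascular markers had 5 of 7 below 0 (median -0.11, adjusted p = 0.772), with Eng at -0.53 ± 0.20, the pericyte gene Rgs5 at -0.37 ± 0.14 and the efflux pump Abcg2 at 0.52 ± 0.23. The cell cycle inhibitor Cdkn1a, which belongs to the cell cycle and the glucocorticoid-responsive lists, stood at -0.51 ± 0.18; those lists had 7 of 12 and 5 of 8 genes below 0 (adjusted p = 0.819 for each). Glrb was the only member of a list tested at this time past a threshold adjusted over the list alone, in the GABA and glycine receptor list (6 of 9 below 0, median -0.02, adjusted p = 0.772), which had the smallest p by fry (0.00439, adjusted p = 0.127).

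At 192 h, the higher group was led by the neuronal kinesin Kif5a (1.05 ± 0.28, n = 2), the phospholipid synthesis enzyme Cds2 (0.81 ± 0.21), Castor2 of the arginine-sensing arm of the mTORC1 pathway (0.67 ± 0.20) and Gad2, which makes the inhibitory transmitter GABA (0.59 ± 0.15). The Riken gene 1700054O19Rik (0.59), the syndecan Sdc4 (0.50), the potassium channel Kcnh7 (0.49) and the collagen receptor Ddr2 (0.44) followed. The lower group was led by Spg21 (-1.08 ± 0.29) and Zpbp (-0.68 ± 0.19), followed by Bhlha15, Sncaip, whose product binds alpha-synuclein, Emc9, Trmt2a, 1700006J14Rik and the galactose enzyme Galt, at -0.34 to -0.41. The adjusted p of each was 1.00. Kif5a rested on replicate 4, at 1.99 against 0.11 in replicate 3, as did Cds2 (1.35 against 0.27), Castor2 (1.15 against 0.19) and Zpbp (-1.11 against -0.24), while Spg21 rested on replicate 3 (-1.86 against -0.31 in replicate 4). Gad2 stood at 0.70 in replicate 4 and 0.49 in replicate 3. All 8 lower oligos lay in column 1 of the blocks in the printing used for replicate 4, which held 26.7% of the tested oligos (random draws, p = 3e-04, adjusted p = 9e-04), and their mean was -0.33 with loess within blocks in place of -0.50.

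Of 2764 oligos tested at 192 h, limma called 0 (93 at an unadjusted p under 0.05, 82 higher and 11 lower, against 138.2 from chance alone), as did limma with trend and robust settings (85 unadjusted) and the fit with arrays as observations, which tested 5586 oligos (199 unadjusted). The interval of 99.6% of the oligos lay inside -1 to 1. Without the 18 h replicate of the widest log2 ratios (SD 0.354), which enters the shared spread, limma still called 0 at 192 h. However, 143 oligos then had an unadjusted p under 0.05, and the smallest adjusted p was 0.0585. Leaving out replicate 3, the only replicate on another printing, gave 19 calls among 6709 oligos, 17 higher and 2 lower, from replicate 4 alone. That value assumes that a lone replicate varies like the other time points.

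Of 24 lists tested at 192 h, the same 2 lists passed as at 18 h, here toward lower values: oxidative phosphorylation (23 of 26 below 0, median -0.08, adjusted p = 0.00294) and cytosolic ribosomal proteins (15 of 17 below 0, median -0.11, adjusted p = 0.00396). Both calls were lost with an estimated correlation (adjusted p = 0.891 for each). Fry gave an adjusted p of 0.873 for each, but with the 2 replicates of this time alone it has little power to pass any list. Ndufb5 (-0.28 ± 0.16), Uqcrb of complex III (-0.25 ± 0.15), Rps25 (-0.29 ± 0.14) and Rpl11 (-0.21 ± 0.14) had the smallest p among their members, and 0 passed adjusted over the list alone. The shift was larger in replicate 4 (-0.18 ± 0.02 and -0.16 ± 0.03, SEM over genes), with -0.01 ± 0.02 and -0.02 ± 0.03 in replicate 3, and without replicate 4 neither list passed. With loess within blocks both replicates lay below 0: -0.11 in replicate 4 and -0.05 in replicate 3 for oxidative phosphorylation, and -0.13 and -0.05 for ribosomal proteins.

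The remaining lists at 192 h did not pass, although without replicate 3 pan-neuronal genes, glutamate receptors and the postsynaptic density, microglia markers and proteasome subunits did, from replicate 4 alone. Pan-neuronal genes had 6 of 9 above 0 (median 0.07, adjusted p = 0.517), with the postsynaptic scaffold Dlg4 (0.45 ± 0.23), Camk2a (0.32 ± 0.18) and Syn1 (0.31 ± 0.18). Synaptic vesicle genes had 10 of 14 above 0 (median 0.05, adjusted p = 0.517), led by Sv2c (0.40 ± 0.16). Excitatory cortical neuron and layer genes had 3 of 7 above 0 (median -0.01, mean 0.04, adjusted p = 0.907), potassium, sodium and calcium channels 3 of 8 (median -0.04, mean 0.01, adjusted p = 0.898) and GABA and glycine receptors 4 of 8 (median 0.00, mean 0.02, adjusted p = 0.907). Oligodendrocyte and myelin genes had 5 of 7 above 0 (median 0.11, adjusted p = 0.517, and 0.0527 by fry, the smallest of any list by that test), with Olig2 at 0.24 ± 0.15 and Sox10 at 0.22 ± 0.15. Astrocyte markers had 6 of 9 above 0 (median 0.09, adjusted p = 0.781). Gad2 was the only member of a list tested at this time past a threshold adjusted over the list alone, in the GABAergic interneuron list (4 of 8 above 0, median -0.04, mean 0.05, adjusted p = 0.954). Glucocorticoid-responsive genes were split 3 and 3 (adjusted p = 0.781), and cytokine, chemokine and NF-kB genes had 4 of 5 above 0 (median 0.05, adjusted p = 0.858), with Relb at 0.19 ± 0.16. The immediate early gene Arc stood at 0.36 ± 0.15; its list had 4 measured genes and was not tested.

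**Figure D2:**
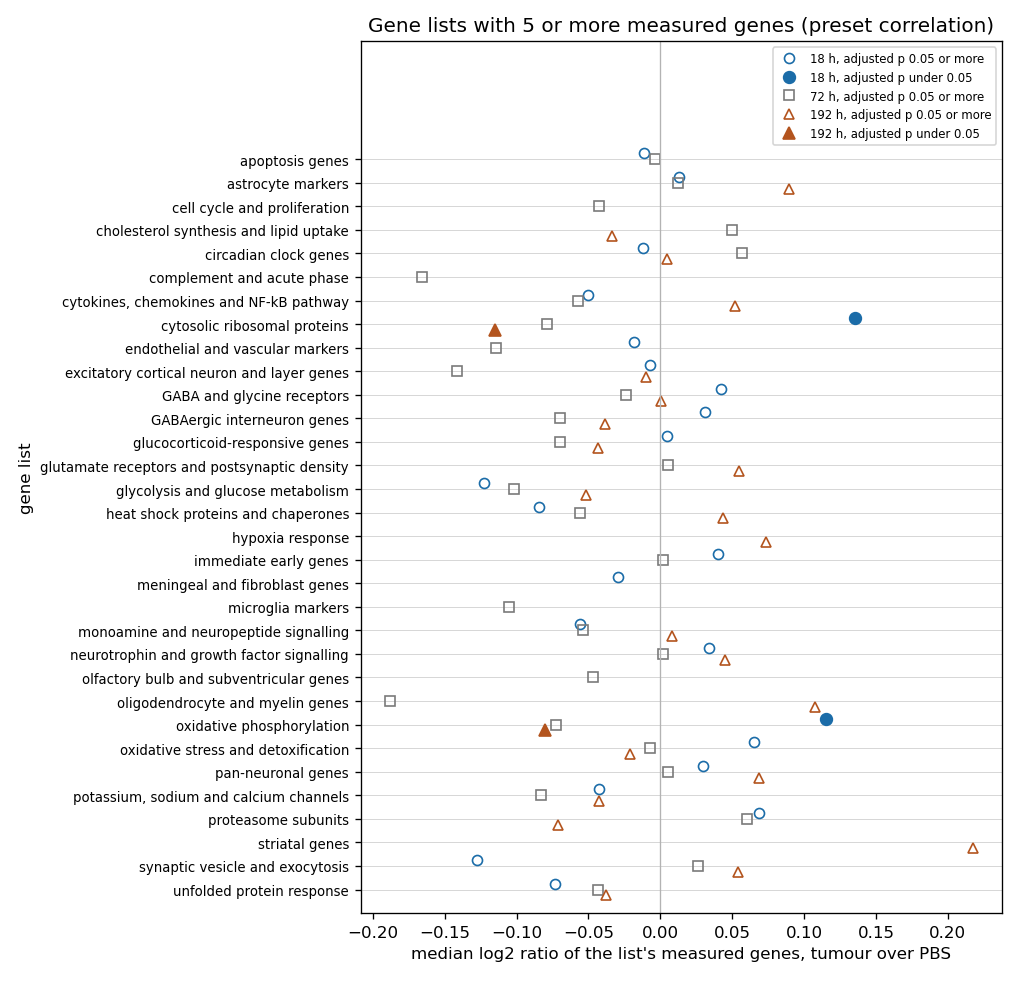
Median log2 ratio of tumour over PBS (horizontal axis) of the measured genes of each list tested at 18 h (circles), 72 h (squares) and 192 h (triangles); filled symbols have an adjusted p under 0.05 with a preset correlation. Only cytosolic ribosomal proteins and oxidative phosphorylation are filled, at 0.14 and 0.12 at 18 h and at -0.11 and -0.08 at 192 h, and neither held with an estimated correlation.

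Averaged over the time points, limma called 0 of 1232 oligos (25 at an unadjusted p under 0.05, 18 higher and 7 lower, against 61.6 from chance alone), limma with trend and robust settings called 0 (22 unadjusted) and the fit with arrays as observations 0 of 4885 oligos (136 unadjusted). The interval of an oligo reached 0.18 to each side at the median, and every tested oligo had an interval inside -1 to 1. Genes are named here only if they have 1 sign in every replicate measured, so that agreement by itself shows nothing. Paqr7, a membrane progestin receptor, was above 0 in 7 of 7 replicates at 0.18 ± 0.08 (adjusted p = 0.997). The cytoskeletal GTPase Septin7 (-0.29 ± 0.10), the stress kinase Map2k4 (-0.24 ± 0.09) and the transcription factor Yy1 (-0.15 ± 0.08) were below 0 in 6 of 6 replicates with a value (adjusted p = 0.997 for each). A single 18 h replicate carried much of each: Septin7 stood at -0.94 in replicate 5, and Map2k4 at -0.80 and Yy1 at -0.44 in replicate 4, with the other replicates at -0.02 to -0.30. With loess within blocks Septin7 averaged 0.0081. None of the 6 lists tested passed, the smallest adjusted p being 0.653. Oprl1, the nociceptin receptor, had the smallest p of the monoamine and neuropeptide list at -0.20 ± 0.08.

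The time points were also set against each other. By limma's F test 0 of 1232 oligos differed (52 at an unadjusted p under 0.05, against 61.6 from chance alone); with trend and robust settings 0 (46 unadjusted) and with arrays as observations 0 of 4885 oligos (207 unadjusted). The genes of smallest adjusted p (0.947 for each) were Prelid3b (-0.09 ± 0.14 at 18 h, 0.83 ± 0.17 at 72 h, -0.13 ± 0.17 at 192 h), 1700054O19Rik, Ncbp2, Nin, Ptov1, Nkx6-3, Arid5b, the calcium channel Cacna1i (-0.34 ± 0.14, 0.05 ± 0.17 and 0.45 ± 0.17), Aftph and the late endosome GTPase Rab7. Across genes the log2 ratios of 18 and 72 h correlated at r = 0.0392 (2061 oligos), those of 18 and 192 h at -0.223 (1610 oligos) and those of 72 and 192 h at -0.0575 (1933 oligos), with an SD over the replicate pairs of 0.0734, 0.123 and 0.0482. Without replicate 4 of 192 h, r for 18 and 192 h was -8.3e-05.

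Between time points, the oxidative phosphorylation genes measured at every time lay lower at 72 h than at 18 h (17 of 19 genes, median difference -0.15, adjusted p = 2.5e-05) and lower at 192 h than at 18 h (16 of 19, median -0.23, adjusted p = 2.1e-06). With an estimated correlation the adjusted p was 0.672 and 0.358. The ribosomal protein genes were lower at 192 h than at 18 h in 7 of 8 (median -0.19, adjusted p = 0.0151, and adjusted p = 0.358 with an estimated correlation). Of the 6 lists tested, none differed between 72 and 192 h (smallest adjusted p = 0.794). The list differences were not run under the alternatives or with a replicate left out.

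**Figure D3:**
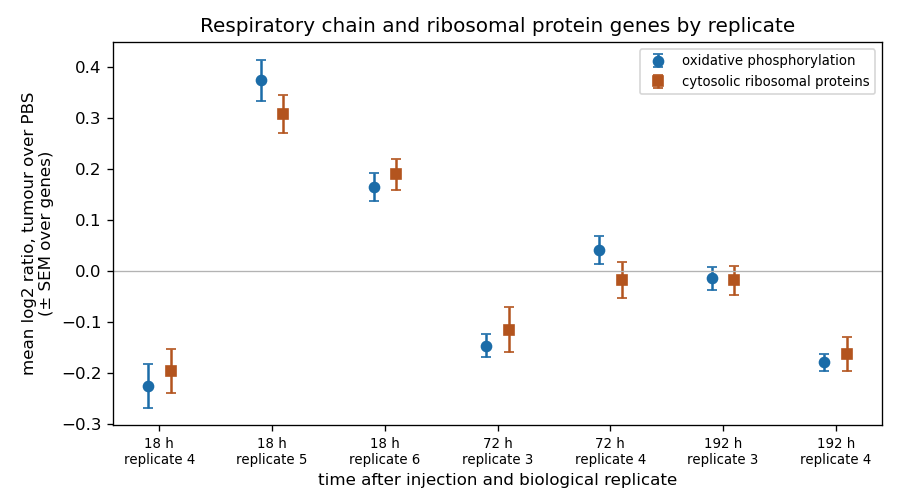
Mean log2 ratio of tumour over PBS (vertical axis, ± SEM over genes) of the oxidative phosphorylation genes (circles) and the cytosolic ribosomal protein genes (squares) in each of the 7 biological replicates. At 18 h both lists went from -0.22 and -0.20 in replicate 4 to 0.37 and 0.31 in replicate 5. In replicate 4 of 72 h they lay on opposite sides of 0, at 0.04 and -0.02.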

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

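In this part, the tests of slide position, list brightness and single replicates were chosen or changed after results had been seen; the other splits of the samples were planned.

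A test of the difference between time points singled out 2 gene groups with roles in energy supply and protein synthesis. Oxidative phosphorylation genes had a median difference of -0.15 between 72 and 18 h (adjusted p = 2.5e-05) and of -0.23 between 192 and 18 h (adjusted p = 2.1e-06), and cytosolic ribosomal protein genes of -0.19 between 192 and 18 h (adjusted p = 0.0151). None held with an estimated correlation (adjusted p = 0.672, 0.358 and 0.358). Only 6 lists had enough genes for this test. The list differences were not run under the alternatives or with a replicate left out. They rest on the values at 18 h, where median centring turned both medians negative (-0.18 and -0.13).

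Both lists lay above 0 at 18 h and below 0 at 192 h. At 192 h, equally bright genes outside the lists had a mean of 0.03 ± 0.02 beside oxidative phosphorylation and 0.03 ± 0.03 beside ribosomal proteins (SEM over 2 replicates). That is a share of the list mean of at most -0.256. In replicate 4 they stood at 0.0026 and 0.0009, while the lists stood at -0.18 and -0.19. They thus showed no such shift in these samples, but an SEM over 2 replicates is too loose to exclude brightness. At 18 h brightness stays open, as equally bright genes had -0.05 ± 0.07 (a share of at most -0.472) and reached -0.18 in replicate 4. Random lists matched on brightness, tested first, decide nothing because the genes of a list are correlated. With loess within blocks the 2 medians at 192 h kept a share of 0.887 of their mean size, and both lists passed with the preset correlation (adjusted p = 0.00149 and 0.00646). That share pools opposite moves. Oxidative phosphorylation went from -0.18 to -0.11 in replicate 4 and from -0.0019 to -0.05 in replicate 3. Ribosomal proteins went from -0.19 to -0.13 and from -0.02 to -0.05. The correction thus changed each replicate, and what was left below 0 argues only against slide position as the whole cause there. With an estimated correlation both lists passed neither before (adjusted p = 0.891 for each) nor after (adjusted p = 0.869 and 0.403). At 18 h slide position stays open: the median kept a share of 0.181 for oxidative phosphorylation (0.12 to 0.02) and of 0.736 for ribosomal proteins (0.14 to 0.10), the mean over 3 replicates went from 0.10 ± 0.18 to 0.08 ± 0.07 and from 0.11 ± 0.16 to 0.12 ± 0.10 (SEM over replicates), and both calls ended as the unadjusted p rose to 0.0330 and 0.0103 with 24 and 19 genes in place of 29 and 23 (first tests pooled the lists, with a share of 0.481 at 18 h and 0.658 over both times). The time after the injection of tumour cells stays open as the biological explanation, and cannot be told apart from single animals or RNA extracts: in 2 of 2 lists the 18 h replicates lay on both sides of 0 by more than 2 standard errors over genes, which decides nothing because the genes are correlated (0.513 and 0.492).

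The 3 replicates at 18 h allow 4 sign patterns, too few for a share under 0.05; the labelled one gave 0 genes and 2 lists, and the highest of the others gave 33 genes and 2 lists, with 3 of the 4 patterns at 2 lists or more. For the average over time 64 of 64 sign patterns gave at least the 0 genes and 64 of 64 at least the 0 lists of the labelled one, with up to 22 genes and 2 lists in the others. Every pattern reaches a count of 0, so this decides nothing about chance. Sign patterns that call many more genes than the labelled one, 33 at 18 h and 22 on average, may point to a structure of the samples, which was not tested. At an unadjusted p under 0.05, the labelled pattern gave 214 oligos at 18 h, against up to 342 in the others; on average it gave 25, and 61 of the 64 patterns gave at least as many, up to 129.

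The poly A arrays, outside the comparisons, held calls under their labelled direction: 18 oligos at 18 h and 2 at 72 h passed in limma, every one of them lower. These arrays have no labelled dye swap and their names could not be matched to the spots, so the genes are not named. Of 15 groups of 4 to 10 values tested for a sample far from the others, none stood out. In groups this small that clears no single array. The block explained 60.0% of the variance on the Cy3 array of replicate 3 at 192 h, against a median of 11.0%. Replicate 4 of 18 h had the widest log2 ratios (SD 0.354).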

How the results depend on the processing

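The alternatives with any saturated pixel, all saturated spots, 1 array of a swap or block loess combined with a dye term were chosen after seeing the data; the cause of the changes below was not tested unless stated. The count of 0 genes at a time point, on average and between times held under all alternatives but these: median centring gave 8 genes at 18 h and 1 at 192 h, the poly A replicates alone 18 at 18 h and 2 at 72 h, and the 12-array printing alone 19 at 192 h, 1 on average and 1 between times. Leaving out 1 replicate gave 0 genes at 18 h, 0 to 1 at 72 h (1 without replicate 4 of 72 h), 0 to 19 at 192 h, 0 to 1 on average and 0 to 1 between times, the highest 3 without replicate 3 of 192 h, which is also the only replicate outside the 12-array printing. In these a lone replicate was assumed to vary like the other times. At 192 h on the 12-array printing alone Kif5a (1.99, adjusted p = 0.00478) and Cds2 (1.35, adjusted p = 0.0362) passed, and under median centring Mitd1 (0.99, adjusted p = 0.0261) and Dlx3 (-0.91, adjusted p = 0.0416) at 18 h and Spg21 (-1.05, adjusted p = 0.0218) at 192 h. Local background subtraction equals the values used and moves nothing. With the replicate number as a block, only replicates numbered 3 and 4 could stay, which left replicate 4 alone at 18 h. That fit therefore decides nothing about differences between times. The replicate numbers were not taken to pair the samples. Same-numbered replicates correlated in their deviations at -0.0867 for 18 and 72 h, -0.106 for 18 and 192 h and -0.000194 for 72 and 192 h. In the last pair 2 replicates per time mirror each other and give a single value.

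Both lists called at 18 h passed in the alternatives not named here. Ribosomal proteins alone passed with the earlier poly A array turned, with scan 3 alone and with any saturated pixel left out (1 list each). With all 12 replicates and the poly A term ribosomal proteins passed, and with 1 array of a swap or arrays as observations oxidative phosphorylation, each beside heat shock proteins and chaperones (2 lists). Neither passed with all 12 replicates without the term (1 other list, heat shock proteins and chaperones), with median centring (3 other lists: the same, pan-neuronal genes and synaptic vesicle genes), and with normexp, the later poly A array turned, poly A alone, block loess and block loess plus dye term (0 lists). Leaving out 1 replicate gave 0 to 2 lists at 18 h: 0 without replicate 5, and without replicate 6 neither of the 2 but 1 other list, the synaptic vesicle genes. At 192 h both called lists passed in the alternatives not named here, beside 1 other list with arrays as observations or block loess and 4 others on the 12-array printing (6 in all: also microglia markers, pan-neuronal genes, glutamate receptors and proteasome subunits). Oxidative phosphorylation alone of the 2 passed with all 12 and the term (beside microglia markers), and as 1 list with all 12 without it, with the earlier poly A array turned or with scan 2 alone. Neither passed with 1 array of a swap or poly A alone (0 lists) or with the later poly A array turned (1 other list). List results that use the poly A arrays, at any time, decide nothing about these lists, because the names could not be matched to the spots; at 192 h poly A alone is also a lone replicate. Leaving out 1 replicate gave 0 to 6 (the same 6 lists without replicate 3, which leaves the same samples, and 0 without replicate 4 of 192 h). At 72 h 0 lists passed under every alternative. On average 1 list passed with all 12 without the term, 2 with median centring and 1 on the 12-array printing, and 0 to 1 with 1 replicate left out.

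The medians turned with median centring for oxidative phosphorylation (-0.18) and ribosomal proteins (-0.13) at 18 h, and without replicate 5 for oxidative phosphorylation at 18 h (-0.0319, against up to 0.277 with another replicate left out). With scan 3 alone the median for oxidative phosphorylation at 18 h lay just below 0 (-0.00373). With poly A alone the test turned for oxidative phosphorylation (median 0.0256) and ribosomal proteins (median 0.0061) at 18 h and for ribosomal proteins at 192 h (median 0.0315). Of named genes, those that turned with poly A alone were 1700006J14Rik (0.56), 1700054O19Rik (-0.12), Emc9 (0.23), Galt (0.0263), Sncaip (0.23), Spg21 (0.0438) and Zpbp (0.15) at 192 h, Napg (-0.0576) at 72 h, and Fbxl20 (0.12) and Ropn1l (-0.24) at 18 h. Glrb turned with the later poly A array turned (0.30), Mkln1 (-0.11) and Zbed3 (-0.12) on average with all 12 without the term, and Septin7 with block loess (0.0081). Poly A values carry names that could not be matched to the spots. At 192 h poly A alone also rests on 1 replicate of 2 arrays without a labelled swap, assumed to vary like the other times. The turns that use poly A arrays thus say nothing about the named genes. That of Septin7 used the total RNA arrays alone and does bear on it.

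Correlations across genes between times moved as follows. For 18 and 192 h, r was 0.0750 with all 12 and the poly A term, -0.0686 without it, -0.0823 with arrays as observations, -0.0839 and -0.0901 with the earlier or later poly A array turned, -0.0112 with median centring and 0.0234 with poly A alone. For 18 and 72 h it was -0.0551 with 1 array of a swap, 0.155 and 0.117 with all 12 with and without the term, -0.0517 with arrays as observations, -0.103 with median centring, 0.281 with poly A alone, -0.0399 with block loess, -0.0367 with block loess plus dye term and -0.0566 in the authors' value tables. For 72 and 192 h it was 0.00350 with 1 array of a swap, -0.00108 with poly A alone, 0.0472 with block loess, 0.0352 with block loess plus dye term, -0.116 with scan 3 alone and 0.114 in the value tables. Leaving out 1 replicate gave -0.324 to -8.3e-05 (the latter without replicate 4 of 192 h), -0.0546 to 0.0824 (-0.0546 without replicate 4 of 18 h and -0.0466 without replicate 4 of 72 h) and -0.103 to 0.0548 (0.0548 without replicate 4 of 72 h) for the same pairs.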

Other observations

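In this part, the tests of slide position for the oligos at 72 h, of spot signal, of a common dye effect and of the dye orientation were chosen or changed after results had been seen; the test of slide position in the dye swaps was written before.

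Groups of genes left out above gave these values, none of them past the threshold as a list. At 18 h the unfolded protein response had 6 of 7 genes below 0 (median -0.07, adjusted p = 0.599), among them the endoplasmic reticulum chaperone Canx (-0.40 ± 0.20) and Ppp1r15a (-0.20 ± 0.13), while proteasome subunits had 8 of 13 above 0 (median 0.07, adjusted p = 0.494; Psmb3 0.25 ± 0.12). Oxidative stress and detoxification genes had 6 of 8 above 0 (median 0.07, adjusted p = 0.834), with catalase (Cat, 0.35 ± 0.15) and superoxide dismutase (Sod1, -0.37 ± 0.19) on opposite sides. Monoamine and neuropeptide genes had 11 of 16 below 0 at 18 h (median -0.06, adjusted p = 0.851) and 9 of 14 at 72 h (median -0.05, adjusted p = 0.772), with Oprl1 at -0.30 ± 0.14 and -0.36 ± 0.14. Circadian clock genes were split 4 and 4 at 18 h (adjusted p = 0.923) and had 6 of 7 above 0 at 72 h (median 0.06, adjusted p = 0.772; Per2 0.15 ± 0.15). Glycolysis genes had 3 of 5 below 0 at 18 h (median -0.12, adjusted p = 0.889), 4 of 7 at 72 h (median -0.10, adjusted p = 0.819) and 6 of 9 at 192 h (median -0.05, adjusted p = 0.517).

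Single members of smallest p included Ido1, an enzyme of tryptophan breakdown listed here among striatal genes (0.47 ± 0.15 at 18 h), the spindle checkpoint kinase Bub1b (0.44 ± 0.15 at 18 h; adjusted p = 0.0369 and 0.0412 over the 4 measured genes of their lists alone), the collagen hydroxylase P4ha1 of the hypoxia list (-0.35 ± 0.13 at 18 h) and Mcl1, which restrains apoptosis (-0.40 ± 0.19 at 18 h). At 72 h they included Cplx1, a regulator of vesicle fusion (0.50 ± 0.18), the proteasome subunit Psmb6 (0.39 ± 0.16) and Eomes (-0.34 ± 0.15), and at 192 h the survival factor Bcl2l1 (0.37 ± 0.15) and the calcium channel Cacna1a (0.30 ± 0.16). Interferon response, antigen presentation, blood leukocyte, erythroid and choroid plexus genes had fewer than 5 measured members at every time, so 5 of the 37 lists were never tested. Of their members at 18 h, Cd79b (0.26 ± 0.13) and Cd79a (-0.26 ± 0.18) went opposite ways, and Isg20 stood at -0.19 ± 0.16, Foxj1 at -0.08 ± 0.16 and Calr at 0.08 ± 0.15.

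Among the oligos of smallest p at 72 h, the 8 higher ones may owe part of their size to their place on the slide: random draws crowded as much into 1 row or column of blocks with p = 1e-04, the smallest 10000 draws can give. Their mean went from 0.68 to 0.44 with loess within blocks. The 8 lower oligos had 2 in the line least likely by chance, row 2 of the blocks (random draws, p = 0.877). The mean of these lower oligos went from -0.58 to -0.48. Unusual signal argues less, since 12.5% of the 16 oligos lay in the lowest or highest 10% of mean signal, against 20% by chance. An effect of the tumour on these genes stays open.

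Both arrays of a labelled swap, read as tumour over PBS, should run the same way, and in 6 of 7 swaps they ran opposite ways, for which slide position does not account as a whole, as with loess within blocks the median r stayed at -0.254 and 6 of 7 swaps below 0, although that of replicate 3 went from -0.597 to -0.192 at 192 h and from -0.484 to -0.348 at 72 h. A dye effect of single oligos common to all arrays is a candidate explanation: 9 of 1232 oligos passed for channel B over A averaged over the swaps (221 unadjusted), with an SD of 0.20 against 0.08 for tumour over PBS. Channel B over A correlated within swaps above its correlation with other replicates by 0.113 ± 0.101 (SEM over 7 swaps), which leaves this open; a first bound of 0.1 on the difference of the medians, which was 0.106, was replaced because it took no account of this spread. In the fit of arrays as observations with a dye term per oligo, the consensus correlation of both turned arrays of a swap was -0.0079. That value is taken per oligo from what the time and dye terms leave over. It therefore cannot be set beside the r across oligos and does not show whether the arrays of a swap agree. A dye term would also take up the effect of the tumour if the orientations were not as labelled. With the dye effect of the other replicates removed the r of the 7 swaps lay below 0 (median -0.303), but the removal itself lowers r. Array pairs from different replicates treated alike had a mean of -0.186, and the swaps differed from them by -0.0997 ± 0.0909 (SEM). In 200 simulations with 1 dye effect on all arrays and independent noise the medians were -0.195 to -0.141, all above that of the swaps. The simulated arrays held no effect of slide position. Single real pairs from different replicates ranged from -0.424 to 0.148. The simulations thus leave open whether the swaps could come from a common dye effect. Arrays hybridised in 1 orientation but labelled as swaps cannot be told apart from it, because channel B over A correlated at a median of 0.274 within swaps and no table shows the dyes independently of the labels; in that case the 9 oligos above would hold the effect of the tumour together with any dye effect, in place of the 0 of 1232 reported for tumour over PBS.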
